A study of Mus musculus with 2 samples.

How the data were processed

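Single-cell RNA was measured from the 5′ end of transcripts (10x Genomics) in hippocampi of 4-week-old mice, in 2 libraries: 1 of wild-type mice and 1 of mice with a Crlf3 mutation. Each library pooled 4 hippocampi of 2 mice before the droplet run, after enzymatic dissociation, removal of debris and myelin, and a sort for live cells. Per the labels, the authors processed the reads with Cell Ranger 6.1.1 against the mm10-2020-A reference, and Partek is listed without a role or version. The deposited matrices hold raw UMI counts per gene and barcode, without normalization, for the barcodes kept by the authors' cell calling. The files carry no annotation of cell types and no map from cells to animals, so each genotype was taken as 1 library.

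The wild-type matrix held 51328178 UMIs in 7713 barcodes and the mutant matrix 43103469 UMIs in 5720 barcodes, over 32285 genes. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, 7246 and 5353. Scrublet (scanpy 1.11.5, expected doublet rate 0.06, run in each library) called 118 doublets (1.63%) in the wild-type library and 80 (1.49%) in the mutant library, which were removed. Doublets that it did not call stay in the data. The filtered libraries held 7128 and 5273 cells with a median of 6201.5 and 7382 UMIs per cell.

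Both libraries were clustered together without batch correction, on 2000 variable genes chosen without Crlf3 and the sex-linked genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, resolution 1.0). A cluster was named, as resembling a cell type, from 19 marker sets fixed before the data were examined. It needed a score of at least 0.5 and at least 3 detected markers. A marker counted as detected where its summed level in the cluster was at least 0.25 of its highest level in any cluster. It stayed unnamed where its 10 leading genes by fold held more markers of another class than of its own. A cluster with median UMIs far below the library's and no own marker among those genes also stayed unnamed. The scoring rule, unlike the markers, was set after the files were read. Neural progenitor-like and neuroblast-like clusters form the neuron lineage. The check of clusters kept 1 cluster, led by mural genes and scored as endothelial, out of both classes (33 wild-type and 22 mutant cells).

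UMI counts were summed over the cells of a class in each library and given as CPM, the UMIs of a gene per 1e+06 UMIs of the class. Log2 ratios are mutant over wild type with a pseudocount of 10 CPM. With 1 library per genotype no test was possible, and no p-value is given. Sums of counts carry exact Poisson 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. These intervals cover counting error only, not differences between animals, dissociations or sorts. Those of summed counts also leave out the uneven spread of UMIs over the cells of a class. A count of 0 was kept as 0, with only the pseudocount added in log2 ratios. To compare shares of cells with a Crlf3 UMI, each cell was thinned to 2000 UMIs and shallower cells were left out, 164 in the wild-type and 120 in the mutant library.

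Genes were named by a rule fixed before the data were examined. In each class with at least 100 cells in each library, a gene needed at least 50 CPM and 30 UMIs in the library where it was higher. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes, receptor segments, and markers of other classes were left out. The 10 highest and 10 lowest log2 ratios in the neuron lineage, the 5 highest and 5 lowest in the other classes, and Crlf3 were named, except that 1 gene met by the rule in the choroid plexus class is not described. Of each gene list, up to 4 measured members with the largest absolute log2 ratio could be named. The 34 gene lists were fixed before the data were examined. Of their 590 genes, 585 matched 1 gene symbol, 3 matched none and 2 matched more than 1. A list is described by the median log2 ratio of its measured members and the percentile of that median among 10000 random lists of the same size and expression. The percentile describes these 2 libraries and is no test. Members are counted as higher or lower at 1.5 times.

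The list medians given in the text, 36 of those measured in the 7 classes, were selected after the medians and their values under the alternatives had been seen. The other 121 are not described. Some medians had a main counting interval that excluded 0 and took the other sign, by any amount, in at least 1 alternative. Under the alternatives chosen before the data were examined, these were 4 of the 36 and 12 of the 121. Under the alternatives added later, these counts were 8 and 22. Medians whose main interval held 0 are not in these counts. Counting every change of sign, 9 of the 36 changed with the stricter cell filter and 9 with a class per cell from marker scores. In cells with Xist and no Y transcript, 11 of 34 changed.

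The log2 ratios, intervals and percentiles were tested on simulated data. Poisson counts were drawn at the real sums of the neuron lineage, microglia, astrocytes and endothelial cells, with 200 genes changed by known folds. In the simulated neuron lineage, of 4266 genes, 100% of the 100 genes changed 1.5-fold had the right sign, with a median error of 0.07 on the log2 scale. None of the 4066 unchanged genes was 1.5-fold apart, and the intervals held the true value for 95.3% of the genes. Such draws follow the same Poisson counting that the intervals assume, so this coverage was set by the design. They hold no variation between animals or between cells. In the real wild-type neuron lineage, the top 5% of cells held 71.2% of the UMIs of homeostatic microglia genes, against 12.3% for an even spread.

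The alternatives chosen before the data were examined were a looser and a stricter cell filter, no doublet removal, Leiden resolutions 0.5 and 2.0, centring of genes within each library, a class per cell from marker scores, thinning to 2000 UMIs, trimmed-mean scaling, CPM without abundant gene groups, the mean of per-cell CPM, a pseudocount of 1 CPM and a minimum of 10 CPM. Added after seeing the data were cells with Xist and no Y transcript, cells with Y transcripts and no Xist, shares outside the choroid plexus class and outside the immune classes, and the removal of non-immune cells with at least 50 UMIs of homeostatic microglia genes. Gene positions came from the GENCODE mouse annotation, release M21. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.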

Results

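The data are UMI counts of single cells from the hippocampi of 4-week-old mice, 1 library of wild-type mice and 1 library of mice that carry the L389P change in Crlf3, the gene of cytokine receptor-like factor 3. Each library pooled 4 hippocampi of 2 mice. After filtering, the wild-type library held 7128 cells and 49301742 UMIs and the mutant library 5273 cells and 41692716 UMIs. The study's title concerns neuronal deficits, and the comparisons below set the cells of the neuron lineage, the other cell classes and the expression of each class side by side. There are no replicates, so no difference was tested, and every interval covers counting error only.

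Microglia-like cells made up most of both libraries, and the cells of the neuron lineage were neural progenitor-like cells and neuroblast-like cells. No cluster met the marker rule for mature excitatory or inhibitory neurons, oligodendrocyte precursors or oligodendrocytes, so nothing is reported on those types. The progenitor-like cluster was led by the cell cycle genes Top2a and Mki67, and a small neuroblast-like cluster was led by Dlx6os1, Dlx1 and Dlx2, genes of the inhibitory neuron lineage. Among the microglia-like clusters, 1 was led by the chemokine genes Ccl4 and Ccl3 (706 wild-type and 583 mutant cells) and 1 by the heat shock gene Hspa1b (751 and 293 cells). Another was led by Nrgn, a gene of the excitatory neuron marker set, with the microglial genes P2ry12 and Siglech among its leading genes (397 and 478 cells).

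Neuron-lineage cells held a larger share of the mutant library than of the wild-type library. They were 208 of 7128 wild-type cells (2.92%, interval 2.54 to 3.34) and 261 of 5273 mutant cells (4.95%, interval 4.38 to 5.57), 1.70 times the wild-type share. Progenitor-like cells were 0.982% and 1.69% and neuroblast-like cells 1.94% and 3.26%, so that progenitors formed 33.7% of the wild-type and 34.1% of the mutant lineage. The Dlx-expressing neuroblasts were 9.62% and 11.5% of the lineage. In the cells outside the immune classes, the lineage was 8.05% of the wild-type and 13.4% of the mutant library. In cells with Xist and no Y transcript its share was 3.16% and 4.50%, and in cells with Y transcripts and no Xist 3.93% and 7.85%. Dissociation, myelin removal and the live sort also set such shares, and each was done on pools of a single genotype.

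Among the other classes, choroid plexus-like cells were 6.40% of the wild-type library (interval 5.84 to 6.99) and 3.03% of the mutant library (2.59 to 3.53). Mural-like cells, the pericytes and smooth muscle cells of vessels, were 1.88% (1.58 to 2.22) and 3.21% (2.75 to 3.72), and endothelial-like cells 11.7% (11.0 to 12.5) and 15.4% (14.4 to 16.4). Astrocyte-like cells were 11.7% (10.9 to 12.4) and 9.44% (8.67 to 10.3), border macrophage-like cells 1.18% (0.941 to 1.46) and 0.531% (0.353 to 0.767), and ependymal-like cells 0.786% (0.594 to 1.02) and 0.417% (0.262 to 0.631). The microglia-like share was 61.9% (60.7 to 63.0) and 61.4% (60.1 to 62.8). Its difference, -0.424 percentage points, was 2.43 in cells with Y transcripts and no Xist.

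**Figure D1:**
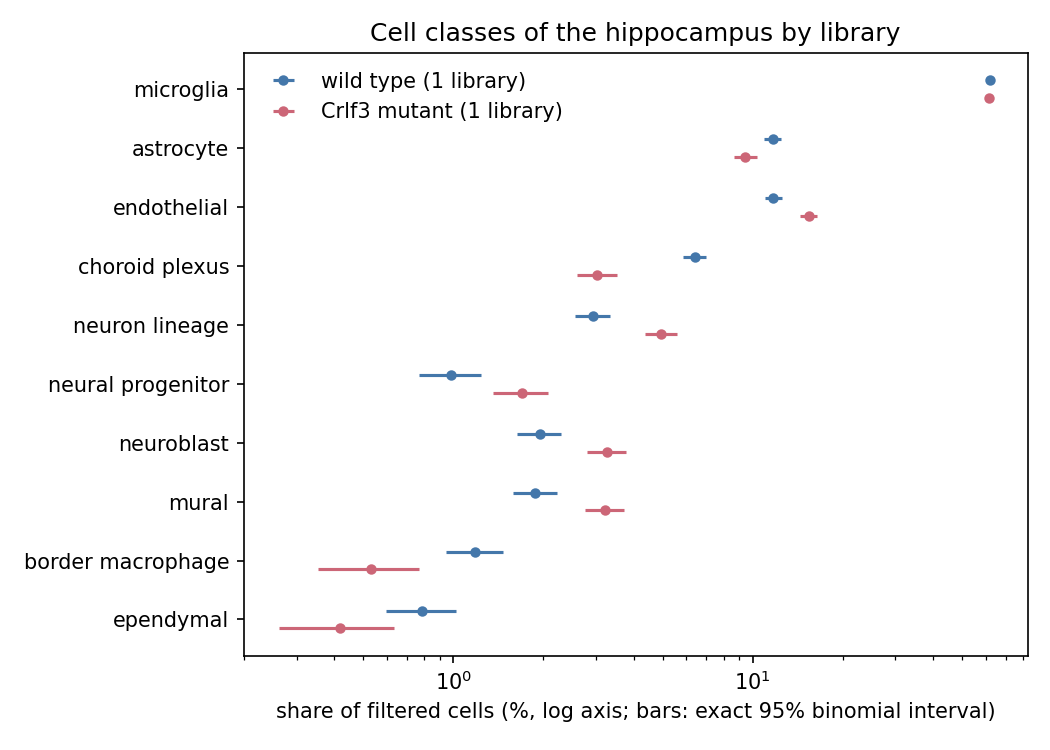
Share of filtered cells in each cell class (%, log axis) in the wild-type and the Crlf3-mutant library, 1 library each, with exact 95% binomial intervals. Neuron-lineage cells were 2.92% of the wild-type and 4.95% of the mutant library, and choroid plexus cells 6.40% and 3.03%.

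Crlf3 transcript levels were close between the libraries. Crlf3 (ENSMUSG00000017561) lies on chromosome 11, positions 80046493 to 80080991 of mm10, on the minus strand. Codon 389 of its principal transcript, which encodes 442 residues, is CTA for leucine in the reference, at positions 80047643 to 80047645 in exon 8 of 8. The counts give no allele, so the genotype itself was not checked. Over all cells Crlf3 stood at 101 CPM (interval 98.5 to 104) in the wild-type and 105 CPM (102 to 108) in the mutant library. In the neuron lineage it stood at 48.9 CPM (39.8 to 59.6, 99 UMIs) and 41.2 CPM (34.5 to 48.9, 131 UMIs). Microglia had 137 and 139 CPM, astrocytes 83.0 and 81.1 CPM, mural cells 66.9 and 62.6 CPM, and endothelial cells 32.1 CPM in both.

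A Crlf3 UMI was found in 34.6% of wild-type and 36.0% of mutant neuron-lineage cells, at median depths of 9263 and 11609 UMIs. Free RNA can give such UMIs in cells that do not express the gene. Choroid plexus cells, which had the lowest Crlf3 level at 15.3 and 18.2 CPM, held a Crlf3 UMI in 14.7% and 21.2% of cells at median depths of 10192 and 12357.5 UMIs. With cells thinned to 2000 UMIs, the shares were 6.76% and 9.38% in the neuron lineage and 2.89% and 2.55% in the choroid plexus. The order of the thinned neuron-lineage shares goes against that of the CPM, so no order is read from them. The log2 ratio in the neuron lineage, -0.20, was 0.35 after thinning and 0.13 in cells with Y transcripts and no Xist.

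In the neuron lineage, the Notch target Hes5 and the late cell cycle genes Cdk1 and Ube2c were higher in the mutant library, and Ccnb1ip1 and the immediate early genes Ier3, Klf2 and Zfp36 were lower. Hes5 turned direction under other settings, to -0.09 with the stricter cell filter and -0.15 with Leiden resolution 0.5. In the main setting, a cluster of 48 wild-type and 34 mutant cells with Hes5 among its leading genes was classed as astrocyte-like. The lineage held 208 and 261 cells in the main setting and 255 and 295 at Leiden resolution 0.5. Neuroblast-like cells were 138 and 172 in both settings, so the lineage grew outside them. Whether the added cells were that Hes5 cluster, and so set the Hes5 value, was not tested. Hes5 (chromosome 4, positions 154960923 to 154962371), a repressor of neuronal differentiation, stood at 37.1 CPM in the wild-type and 120 CPM in the mutant library (log2 ratio 1.46, interval 1.16 to 1.76). The mitotic kinase gene Cdk1 (log2 ratio 0.62) and Ube2c, of the anaphase-promoting machinery (log2 ratio 0.62), were also among the 10 highest. So were Kpna2 of nuclear import (log2 ratio 0.96), the histone gene Hist1h2af (0.78), Igfbp5 (0.75), the oxysterol-binding protein gene Osbp (0.73), the chemokine gene Ccl3 (0.64), the kinase subunit gene Camk2b (0.64) and the cell cycle inhibitor gene Cdkn1a (0.58).

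Ccnb1ip1 (chromosome 14, positions 50789248 to 50807732), known from meiotic crossing over, was the lowest, with 87.5 CPM in the wild-type and 16.1 CPM in the mutant library (log2 ratio -1.90, interval -2.21 to -1.58). The immediate early genes Ier3 (log2 ratio -1.27), Klf2 (-0.69) and Zfp36 (-0.66) were lower in the mutant library, as were the glucose transporter gene Slc2a1 (-1.08) and the histone genes Hist1h3e (-1.03) and Hist2h4 (-1.02). The myeloid genes Cd14 (-1.15), Cd83 (-0.89) and Cebpb (-0.66) completed the 10 lowest. Homeostatic microglia genes reached 2036 CPM in the wild-type and 2102 CPM in the mutant neuron lineage, with a median log2 ratio of 0.05 over 13 genes, and 19 and 22 of its cells held at least 50 such UMIs. Without these cells the log2 ratio was 0.13 for Cd14, 0.25 for Cebpb, -0.44 for Cdkn1a, -0.17 for Camk2b and -0.08 for Cd83. Ccl3 was at -0.33 and Cdkn1a at -0.10 with a class per cell from marker scores, Camk2b at -1.07 in thinned cells, and Hist2h4 at 0.03 in cells with Xist and no Y transcript.

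**Figure D2:**
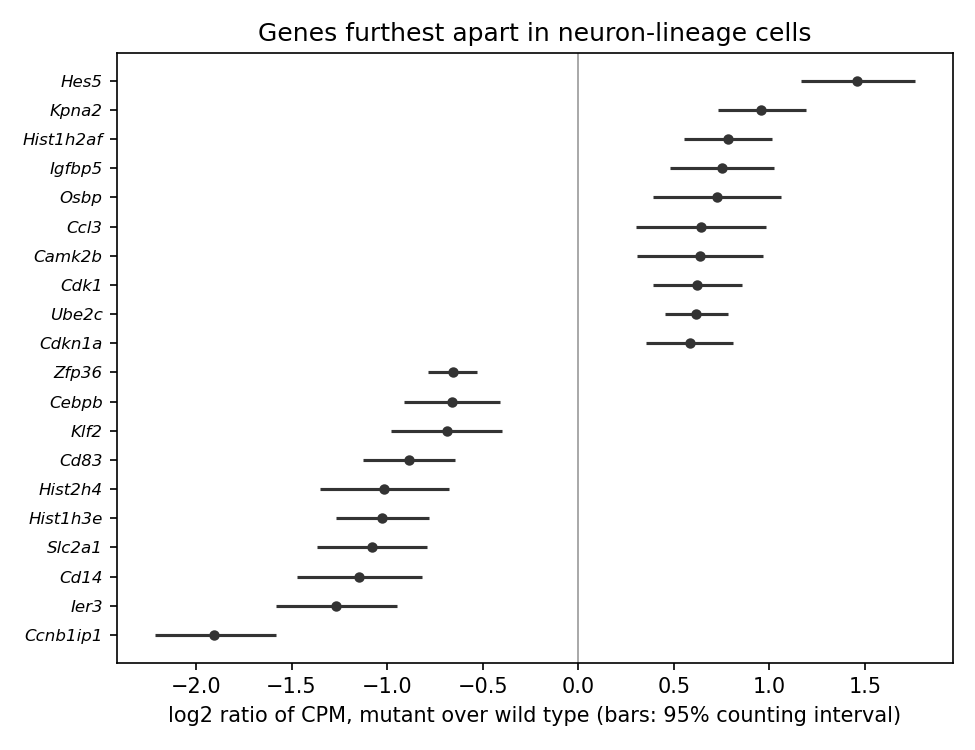
Log2 ratio of CPM, mutant over wild type, of the 20 genes furthest apart in neuron-lineage cells, with 95% counting intervals, from 1 library each. Hes5 is the highest at 1.46 and Ccnb1ip1 the lowest at -1.90.

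Of 17 measured genes of the G2 and M phase, all were above 0 and 2, Cdk1 and Ube2c, were at least 1.5 times higher in the mutant neuron lineage. Their median log2 ratio was 0.37, at percentile 100 of the random lists, and Top2a (0.56) and Kif11 (0.50) were next. Under the alternatives chosen before the data were examined, this median lay between 0.20, in cells thinned to 2000 UMIs, and 0.47. In the progenitor-like cells alone, 19 were measured, 3 were at least 1.5 times higher, and the median was 0.43. That class held 70 wild-type and 89 mutant cells, below the minimum of 100 cells used for the other classes. Of these cells, 14.3% and 14.6% held at least 50 UMIs of homeostatic microglia genes. Without cells holding that many, the median in the lineage was 0.32. The 14 measured S phase genes had a median of 0.00, with none 1.5 times apart. Of 15 immediate early and dissociation response genes, 3 were at least 1.5 times lower and 12 were below 0, with a median of -0.16 (percentile 0.01). In cells with Xist and no Y transcript, the median was -0.031 over the same 15 genes and 0.04 over the genes that reach 50 CPM in those cells. In cells with Y transcripts and no Xist, it was -0.015 over the same 15 genes, so it was near 0 in both subsets. Free RNA and residual doublets enter these sums too. The transthyretin gene Ttr, a choroid plexus transcript, stood at 101 CPM in the wild-type and 17.3 CPM in the mutant neuron lineage.

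Genes that mark young neurons and build neurites lay close between the libraries. None of the 16 immature neuron genes was 1.5 times apart. Their median log2 ratio was -0.05 (percentile 2.05), with Bhlhe22 at -0.33, Neurod1 at -0.28 and Dlx6os1 at 0.48. It was 0.05 with the stricter filter, 0.06 with Leiden resolution 0.5, 0.14 with a class per cell and 0.03 in cells with Y transcripts and no Xist. The 21 measured genes of neurite outgrowth and microtubules had a median of 0.06 (percentile 93.4), with the microtubule regulators Stmn2 at 0.34 and Stmn1 at 0.23, and -0.04 in cells with Xist and no Y transcript. The 13 presynaptic genes had a median of -0.04, with the glutamate transporter gene Slc17a6 at -0.48 and Snap25, of vesicle fusion, at -0.26. In neuroblast-like cells alone, the medians were -0.06 for immature neuron, 0.06 for neurite and -0.01 for presynaptic genes.

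Genes of cytokine receptor signalling were also close in the neuron lineage. The 5 measured genes of JAK-STAT and gp130 signalling had a median of -0.15 (percentile 5.07), with the feedback inhibitor Socs3 at -0.24 and Stat3 at -0.15, and 0.12 in cells with Xist and no Y transcript. None of them was 1.5 times apart. The 15 genes of neural stem cells and progenitors had a median of 0.04, with Hes5 the only member 1.5 times higher. The 7 genes of apoptosis and the p53 response had a median of 0.09, with Ccng1 at 0.55 and Gadd45g at -0.43. Mitochondrially encoded genes had a median of -0.14 (13 genes) and nuclear genes of oxidative phosphorylation 0.06 (28 genes), with none 1.5 times apart.

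In neuroblast-like cells, Clu (log2 ratio 1.97), C1ql3 (1.03), Osbp (1.02), Gpd1 (0.97) and Fam172a (0.84) were the highest in the mutant library. The chemokine gene Ccl4 (-2.43), Ccnb1ip1 (-1.93), the stress transcription factor genes Atf3 (-0.87) and Cebpb (-0.81), and Flrt1 (-0.81) were the lowest. Clu, an apolipoprotein gene abundant in astrocytes, rested on 9 and 108 UMIs and stood at -0.56 with the looser filter, -0.65 with a class per cell, -0.62 in cells with Xist and no Y transcript and -0.04 in cells with Y transcripts and no Xist. C1ql3 rested on 3 cells with a UMI in each library. It stood at -0.19 in thinned cells and -0.94 in cells with Xist and no Y transcript. Homeostatic microglia genes stood at 1367 CPM in wild-type and 1234 CPM in mutant neuroblasts. Without cells holding at least 50 such UMIs, Ccl4 stood at -0.73 and Cebpb at 0.33.

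In microglia-like cells, the chemokine genes Ccl4 and Ccl3 were lower in the mutant library, and most other inflammatory genes and the homeostatic genes were close. Ccl4 stood at 2001 CPM in the wild-type and 1323 CPM in the mutant library (log2 ratio -0.59, interval -0.61 to -0.57) and Ccl3 at 816 and 560 CPM (-0.54). The chaperone gene Hspa1b (-0.56), the hexokinase gene Hk2 (-0.48) and the activation marker gene Cd83 (-0.36) completed the 5 lowest. The cluster led by Hspa1b held 751 of the 4410 wild-type and 293 of the 3240 mutant microglia, so these class-wide values mix clusters in unlike proportions. Of 16 inflammatory cytokine and chemokine genes, 13 were below 0 and 1, Ccl4, was at least 1.5 times lower (median -0.09, percentile 0). The ferritin pseudogene Ftl1-ps1 (0.64), Tob1 (0.41), AY036118 (0.30), the linker histone gene Hist1h1c (0.30) and Csnk1g2 (0.30) were the highest.

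None of the other lists given for microglia had a member 1.5 times apart. The 17 homeostatic genes had a median of 0.03 (0.00 in cells with Xist and no Y transcript), with the phagocytosis receptor Mertk at 0.12. The 11 genes of disease-associated microglia had a median of -0.07, with the growth factor Csf1 at -0.27 and Apoe, a lipid carrier, at 0.21. The medians were -0.04 for 19 immediate early genes, 0.07 for 10 heat shock genes, -0.01 for 14 complement and phagocytosis genes, -0.01 for 8 genes of MHC class I and 0.00 for 8 JAK-STAT genes.

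In astrocyte-like cells, the 5 lowest genes of the mutant library were genes of microglia: Cd83 (log2 ratio -1.51), Ccl4 (-1.46), Crybb1 (-1.32), the lysosomal protease gene Ctss (-1.29) and the complement gene C1qc (-1.21). Of 14 measured homeostatic microglia genes, 11 were at least 1.5 times lower, with a median of -0.96 (percentile 0), Fcrls at -1.25 and Cx3cr1 at -1.24. Cells with at least 50 such UMIs were 6.38% of wild-type and 2.41% of mutant astrocytes. Without them the 5 lowest genes lay between -0.51 (C1qc) and -0.18 (Crybb1) and the median was 0.01, a removal by the same genes that lowers the difference by construction. Without the top 5% of cells, these genes stood at 864 CPM in wild-type and 566 CPM in mutant astrocytes. That removed 42 and 25 cells, while 53 and 12 astrocytes held at least 50 such UMIs, so some wild-type ones remained. Of 17 immediate early genes, 6 were at least 1.5 times lower (median -0.41, percentile 0), with Atf3 at -1.09 and Zfp36 at -0.83, but the median was 0.25 in cells with Xist and no Y transcript. Genes of glutamate, potassium and water handling had a median of 0.05 (15 genes), with the water channel gene Aqp4 at 0.18. It was -0.01 in thinned cells and with the mean of per-cell CPM, -0.07 in cells with Xist and no Y transcript and -0.02 without cells holding microglial UMIs. Cholesterol synthesis (17 genes) had a median of 0.02 and the 3 measured reactive astrocyte genes -0.04. Cideb (0.55), Hist1h4h (0.50), Dynlt1b (0.49), G0s2 (0.47) and Rlbp1 (0.46) were the highest.

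In endothelial-like cells, none of the 17 blood-brain barrier genes was 1.5 times apart. All 17 were above 0, with a median of 0.15 (percentile 99.99), and with the transferrin receptor gene Tfrc at 0.48 and the transcription factor gene Lef1 at 0.29. Osbp (0.62), Tfrc, the matrix gene Ccn2 (0.45), Stmn1 (0.42) and Slc25a4 (0.42) were the 5 highest. The 5 lowest were again genes of microglia and other myeloid cells, C1qc (-1.74), Ctss (-1.59), Olfml3 (-1.53), Fcer1g (-1.49) and Selplg (-1.47), and 11 of 12 homeostatic microglia genes were at least 1.5 times lower (median -1.38). Cells with at least 50 homeostatic microglia UMIs were 2.99% and 1.11% of the class, and without them, by the same construction, the 5 lowest genes lay between -0.81 (Selplg) and -0.098 (Ctss) and the median was -0.015. It was -0.59 with the stricter filter and without doublet removal, and -0.68 in cells with Y transcripts and no Xist. The 4 measured genes of endothelial activation had a median of -0.26, with the adhesion gene Icam1 at -0.75, and 14 genes of the type I interferon response a median of -0.01.

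**Figure D3:**
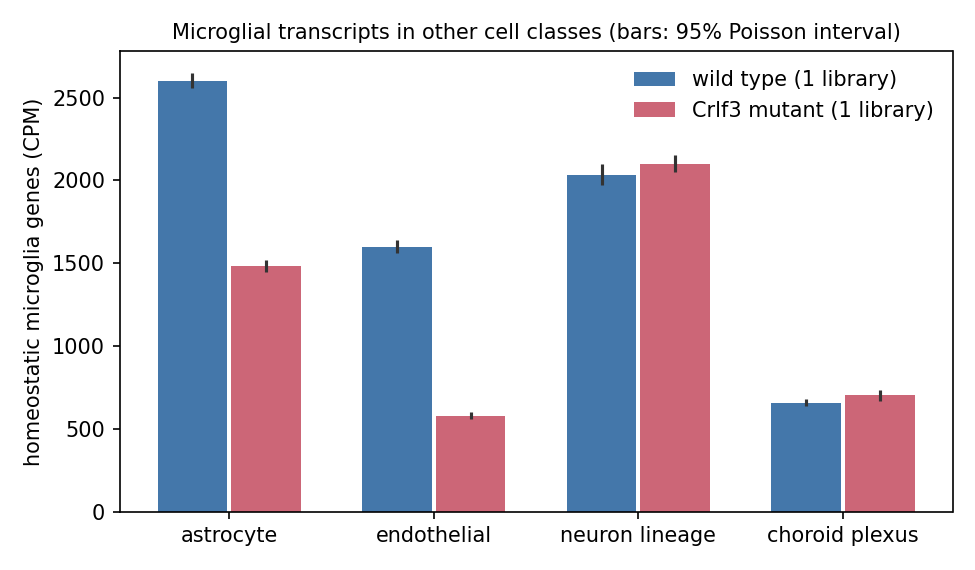
Summed level of 15 homeostatic microglia genes (CPM) in 4 other cell classes of the wild-type and the Crlf3-mutant library, 1 library each, with exact Poisson 95% intervals. Endothelial cells held 1599 CPM in the wild-type and 580 CPM in the mutant library, and choroid plexus cells 660 and 704 CPM.

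In choroid plexus-like cells, the interferon-induced gene Ifitm3 stood at 51.4 CPM in the wild-type and 114 CPM in the mutant library (log2 ratio 1.01, interval 0.80 to 1.23). The neurofilament gene Nefh (1.01), Ppp1r1a (0.76) and Atf3 (0.63) were also among the highest, with Atf3 at -0.46 without cells holding microglial UMIs. The nuclear RNA Malat1 (-1.20), the immediate early gene Fos (-0.77), Cgnl1 (-0.72), Id3 (-0.67) and Emb (-0.60) were the lowest, with Fos at 0.20 in cells with Y transcripts and no Xist. All 13 mitochondrially encoded genes were below 0, with 2 at least 1.5 times lower and a median of -0.50, while 28 nuclear genes of oxidative phosphorylation had a median of 0.06.

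Mural-like cells held the smallest sums. L3mbtl3 (1.495), the collagen cross-linking gene Lox (1.47), Zc3h7a (1.29), Trio (1.18) and Bloc1s4 (1.08) were the highest in the mutant library, each on at most 11 wild-type UMIs. The astrocyte-rich genes Clu (-3.69), Mt3 (-3.41), Gpr37l1 (-2.68) and Apoe (-2.24) and the chemokine gene Ccl4 (-3.69) were the lowest. The 9 genes of the astrocyte marker set, summed, were much closer, at 5275 CPM in wild-type and 4656 CPM in mutant mural cells. Gpr37l1 rested on 32 wild-type UMIs and 1 mutant UMI. Ccl4 stood at 0.14 with the looser filter, 0.49 in cells with Y transcripts and no Xist and 0.03 without cells holding microglial UMIs, and Apoe at 0.67 in cells with Y transcripts and no Xist. Of 12 homeostatic microglia genes 7 were at least 1.5 times lower (median -0.73), a median that was 0.32 with the looser filter, 1.24 with the stricter filter and 2.27 in cells with Y transcripts and no Xist. The 19 immediate early genes had a median of 0.07, which was -0.06 without doublet removal and -0.04 with a class per cell.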

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

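The cells with Xist only, the cells with Y transcripts only, the shares outside the choroid plexus and immune classes and the removal of cells holding microglial UMIs were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers and each genotype has 1 library. The difference in neuron-lineage share, 2.03 percentage points, lay between 1.97 and 2.43 under the 8 settings chosen before the data were examined. The ratio of the shares, 1.70 in the main setting, was lowest at 1.48 with a class per cell, followed by 1.56 at Leiden resolution 0.5. The difference was 1.34 in cells with Xist only (ratio 1.43) and 3.92 in cells with Y transcripts only (ratio 2.00). Outside the immune classes, where both shares are larger, it was 5.30 (ratio 1.66). The other 7 class shares kept their direction under those settings, with the microglia difference at -2.17 after centring genes within each library. In cells with Xist only, the difference was -3.64 for microglia, -0.148 for choroid plexus, 0.682 for mural, -0.123 for border macrophage and -0.0848 for ependymal cells. In cells with Y transcripts only, it was 2.43 for microglia, -6.02 for choroid plexus, -1.50 for border macrophage and -0.673 for ependymal cells. These subsets hold fewer cells, and the cause was not tested.

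The Crlf3 log2 ratio was 0.35 in the neuron lineage after thinning, -0.077 over all cells with Xist only, and 0.10 over all cells and 0.13 in the neuron lineage with Y transcripts only. In the neuron lineage, the G2 and M phase median stayed above 0 in all settings, at 0.20 after thinning, 0.58 with Xist only and 0.53 with Y transcripts only. The immature neuron median was 0.05 with the stricter filter, 0.059 at Leiden resolution 0.5, 0.14 with a class per cell and 0.029 with Y transcripts only. The neurite median was 0.088 at Leiden resolution 0.5, 0.22 with a class per cell, -0.042 with Xist only and 0.12 with Y transcripts only. The JAK-STAT median was -0.34 with a class per cell and 0.12 with Xist only. The immediate early median with Xist only was 0.04 over the genes that reach 50 CPM in those cells and -0.031 over the genes measured in all cells, so its sign there depends on which genes are counted. With Y transcripts only, it was -0.015 over the genes measured in all cells. For all of these the cause was not tested.

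Single genes that took the other sign in the neuron lineage were Hes5 (-0.091 with the stricter filter, -0.15 at Leiden resolution 0.5), Ccl3 (-0.33 with a class per cell), Cdkn1a (-0.10 with a class per cell, -0.44 without cells holding microglial UMIs), Camk2b (-1.07 after thinning, -0.22 with Xist only, -0.17 without cells holding microglial UMIs), Cd14 (0.32 with Xist only, 0.13 without those cells), Hist2h4 (0.033 with Xist only) and Cebpb (0.25 without those cells). In neuroblasts these were Clu (-0.56 with the looser filter, -0.65 with a class per cell, -0.62 with Xist only, -0.043 with Y transcripts only), C1ql3 (-0.19 after thinning, -0.94 with Xist only) and Cebpb (0.33 without cells holding microglial UMIs). With the looser filter and with a class per cell, no neuroblast held a C1ql3 UMI in either library, so that it gave no direction. In choroid plexus cells they were Fos (0.20 with Y transcripts only) and Atf3 (-0.46 without those cells). In mural cells they were Ccl4 (0.14 with the looser filter, 0.49 with Y transcripts only, 0.031 without those cells) and Apoe (0.67 with Y transcripts only). The cause was not tested.

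The homeostatic microglia median was 0.32, 1.24 and 2.27 in mural cells with the looser filter, the stricter filter and Y transcripts only, 0.012 in astrocytes without cells holding microglial UMIs, a setting that picks cells by the same genes and so lowers the difference by construction, -0.015 in endothelial cells in the same setting, and -0.002 in microglia with Xist only. The mural immediate early median was -0.064 without doublet removal and -0.044 with a class per cell, and the astrocyte one 0.25 with Xist only. The astrocyte median for glutamate, potassium and water handling was -0.007 after thinning, -0.006 with the mean of per-cell CPM, -0.07 with Xist only and -0.019 without cells holding microglial UMIs. The cause was not tested. Of the 79 pairs of a class and a gene named in it, all kept their sign under trimmed-mean scaling, CPM without abundant gene groups, the mean of per-cell CPM and a pseudocount of 1 CPM. A pseudocount cannot change a sign, and trimmed-mean factors were at most 0.065 on the log2 scale, too small to turn these genes. All 79 also kept it without doublet removal, at Leiden resolution 2.0 and after centring genes within each library. At Leiden resolution 0.5 and with the stricter filter 78 did, after thinning 77 and with the looser filter 76. With a class per cell and in cells with Y transcripts only 75 did, and without cells holding microglial UMIs 72. In cells with Xist only, 70 could be computed, since too few choroid plexus cells carried Xist, and 65 of them kept their sign.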

Other observations

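The tests of explanations for the neuron-lineage share and for free microglial RNA were chosen after the result was seen. The test of droplets with a microglial cell and both tests on Xist in the choroid plexus were written before. Genes singled out in the next paragraph were chosen after their values were seen.

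Ccnb1ip1 was lower in the mutant library in most classes, with log2 ratios of -1.90 in the neuron lineage, -1.48 in mural cells, -1.01 in astrocytes, -0.66 in microglia and -0.38 in endothelial cells, and 1.26 in the few ependymal cells. Osbp was higher in most classes, at 0.80 in mural cells, 0.73 in the neuron lineage, 0.62 in endothelial cells and 0.26 in microglia, and at -0.50 in ependymal cells. Ttr was lower outside the choroid plexus, at 336 CPM in wild-type and 33.3 CPM in mutant astrocytes and at 141 and 29.9 CPM in microglia, while choroid plexus cells themselves held 220860 and 204418 CPM. At least 5 UMIs of 6 genes of mature neurons were found in 20 of 4410 wild-type microglia (0.454%, interval 0.277 to 0.7) and in 24 of 3240 mutant microglia (0.741%, 0.475 to 1.10), where an even spread of the same UMIs gives 0.107 and 0.169 cells.

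The neuron-lineage share was higher in the mutant library. A loss of shallow neuron-lineage cells from the shallower wild-type library stays open. The ratio was 1.71 with the looser filter, but that filter did not raise the lineage's cell counts, which were 206 and 261. A shallow cluster of 208 wild-type and 170 mutant cells, with a median of 1115 UMIs, stayed unnamed there, so the ratio cannot decide. Barcodes that the authors' cell calling left out were not seen either. An excess mainly from 1 of the 2 animals of a pool stays open: the smaller lower counting bound of the share ratio was 1.06, but for neuroblasts the ratio was 1.30 (0.905 to 1.87) in cells with Xist only and 2.14 (1.51 to 3.08) in cells with Y transcripts only, and these intervals hold no variation between animals. A yield of cell types that differed between the dissociations and sorts cannot be told apart from the genotype, since each genotype was processed as 1 pool and mural cells also had a ratio of 1.70. An effect of the mutation may contribute and was not tested.

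Transcripts of microglia were lower in astrocytes and endothelial cells of the mutant library. For more free microglial RNA in the wild-type library, the wild-type minus mutant difference in choroid plexus cells was -0.0432 of that in endothelial cells. This value cannot decide: the top 5% of choroid plexus cells held 88.5% and 90.8% of these UMIs in the wild-type and mutant library. Without the top 5%, wild-type and mutant levels were 83.4 and 70.5 CPM in choroid plexus but 241 and 257 CPM in mural cells. Free RNA therefore stays open. Droplets that held a microglial cell beside the other cell, more often in the wild-type library, are a candidate explanation: the top 5% of wild-type cells held 69.8% of these UMIs in astrocytes and 90.7% in endothelial cells. Doublets were called in each library apart, at score thresholds of 0.334 in the wild-type and 0.31 in the mutant library. The endothelial median, -1.38, was -0.59 without doublet removal and with the stricter filter, so its size also depends on how cells were removed. Without the top 5% of cells, the wild-type and mutant levels were 165 and 133 CPM in endothelial cells but still 864 and 566 CPM in astrocytes. In astrocytes this removed 42 wild-type and 25 mutant cells, while 53 and 12 held at least 50 such UMIs. The astrocyte remainder thus still holds wild-type cells with many microglial UMIs, and it cannot show a part that such droplets leave unexplained. The concentration alone does not separate the libraries, since the top 5% held 65.1% and 78.8% in the mutant library, and 71.2% and 76.3% in the wild-type and mutant neuron lineage, where the level was not lower, and no biological explanation was tested.

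Choroid plexus cells were almost without Xist in both libraries: of cells with either kind of transcript, 3.14% in the wild-type and 2.56% in the mutant library had Xist only, against 61.8% and 56.1% in microglia. Cells of both animals with a low Xist level were to give a fitted fraction of cells from a Y-carrying animal of at most 0.7 in each library, and cells nearly all from the male a lower bound above 0.8 in each. The fraction was 0.66 (0.555 to 0.765) in the mutant library, which meets the first and lies below the second, and 0.84 (0.76 to 0.93) in the wild-type library, which meets neither. Since the libraries differ and the labels do not give the sex of the animals, the explanations cannot be told apart.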
